A study of Rattus norvegicus with 12 samples.

How the data were processed

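RNA from the whole ganglionic eminences of 12 rat embryos, 6 homozygous for BACHD and 6 wild type, was measured on Affymetrix rat Gene ST arrays. Per the labels' protocols, the eminences of each embryo were freed of meninges and stored in RNAlater, RNA was extracted with the RNeasy Mini Kit and labelled cRNA was made with the Ambion WT Expression Kit. Per the series' design text, the embryos came from 3 dams and were genotyped from genomic DNA and from transcripts. The submitters' processing notes name Partek 6.4 and RMA, without order or settings. The deposited values are log2 intensities, 1 per probe set and array. Their scale was read from the values, and the background correction and normalization within RMA are not given in the sources used here. RMA usually makes the distributions of arrays alike, which can hide a shift of all genes. The array medians here lay between 7.67 and 7.76. Short probes also compress large differences, so folds may be too small. Depth does not apply to arrays, and their number limited precision. The median standard error of a difference was 0.0576.

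The table held 29214 probe sets. The platform annotation gave 1 gene for 15310, several for 323 and none for 13581, which are unnamed here and may or may not read a gene. Of the probe sets with 1 gene, 15279 matched the RefSeq table of the rat assembly GRCr8 by Entrez number, 31 did not, and no symbol changed. There were 14506 genes. The build of the array design was not known, so the assembly served only for names and for which genes neighbour each other, and no coordinates are given. No probe set was removed, and 198 rows were identical to another row.

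Groups were taken from the labels. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with genotype as the only factor and Benjamini-Hochberg adjustment over all probe sets at 0.05. Differences are homozygous minus wild type on the log2 scale. Htt and whole profiles were tested by exact permutation over all assignments of 6 and 6. The spread within groups was the distance of each array to its group's centre, rescaled for group size where arrays were left out. For its test these distances were permuted as fixed values, without computing new centres for each assignment, so its p is approximate. For gene lists, 1 probe set per gene was used, that with the highest mean, and 36 of 38 lists had at least 5 measured genes and were tested with camera at a correlation of 0.01, adjusted over the lists. The Y-linked list with 2 measured genes and that of the inactive X transcript with 0 were not tested. Clustering of changed genes along the chromosomes was tested against 10000 random draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

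The genes named were set by a rule made, like the lists and most of the other settings, before the data were examined. They were Htt, the 12 genes with the smallest p among those past the threshold in each direction, and at most 2 members per list with the smallest p. Where a gene had several probe sets, the values are those of the set with the highest mean, and disagreement is stated. Other genes are said to be chosen after their values were seen. In simulated data with the spread of these arrays over 29214 probe sets, limma recovered 32%, 60%, 88% and 100% of 50 genes each changed by 0.2, 0.3, 0.5 and 1 on the log2 scale, with 10 false calls among 150. All sizes were planted in the same simulated set, and the larger changes ease the adjusted threshold for the smaller ones. Only 2 real calls differed by over 1.5-fold, so recovery of small changes may be lower in these arrays. The oxidative phosphorylation list, shifted by 0.05, was recovered over 14506 genes. Probe sets were simulated independently of each other, but in the real arrays the estimated correlation within that list was 0.163. The recovery of a list and the share of false calls may therefore not hold for these arrays.

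Other settings tried were a replicate block, a filter on dim probe sets, arrays centred on their medians, quantile normalization, no intensity trend, no variance moderation, array weights, the first residual component as a covariate, a 1.2-fold minimum, leaving out each array, other set tests and other window sizes. Chosen after seeing the data were cyclic loess, only probe sets with 1 gene, leaving out wild type 1 and 2 together, a covariate for the difference of dim and bright probe sets in each array, and the level of Eif2s3 as a covariate. The dam and the sex of the embryos were not used here.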

Results

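Gene expression was measured in the ganglionic eminences of rat embryos at embryonic day 14, the part of the ventral forebrain that gives rise to the striatum and to many cortical interneurons. Medial and lateral eminences were dissected from each embryo. Of the 12 embryos, 6 were homozygous for the BACHD transgene, a bacterial artificial chromosome carrying full-length human mutant huntingtin with 96 CAG repeats, and 6 were wild type. All came from 3 time-bred dams dissected on the same day, and each array held the RNA of 1 embryo. The labels did not give the dam or the sex of each embryo. The study's stated aim was to find early transcriptional changes in transgenic embryos. The 12 arrays had medians between 7.67 and 7.76 on the log2 scale and correlated pairwise with r between 0.994 and 0.998 across probe sets, which are not independent replicates. The medians went along with genotype, from 7.67 to 7.71 in wild type and from 7.69 to 7.76 in homozygous arrays. All homozygous arrays except homozygous 1 had a median above every wild-type array. The SD of the log2 difference between 2 arrays was 0.146 or more in every pair, so no array was a copy of another. Without known repeat measurements for comparison, this cannot show whether 2 arrays held the same RNA. Precision was limited by the number of arrays.

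Htt, the rat gene for huntingtin, was read by 1 probe set and was higher in homozygous embryos. Its log2 intensity was 9.97 ± 0.114 in wild type (SD, n = 6) and 10.26 ± 0.0967 in homozygous embryos (SD, n = 6). The 1.23-fold difference (95% confidence interval 1.13 to 1.33) was larger than the spread between embryos. All 6 homozygous values, from 10.16 to 10.40, lay above all 6 wild-type values, from 9.77 to 10.07. The exact permutation p was 0.00216 (2-sided), the smallest that 6 against 6 can give. The adjusted p over all probe sets was 0.0408 in limma. It rose past 0.05 without wild type 1 (0.0501), 2 (0.0557), 4 (0.0657), 5 (0.0679) or 6 (0.0864), and without homozygous 1 (0.0765), 2 (0.0764), 3 (0.0791), 4 (0.0720), 5 (0.0857) or 6 (0.0712), at log2 differences between 0.26 and 0.32. It also rose past 0.05 with arrays centred on their medians (0.0555), without an intensity trend (0.0890) and in a test without variance moderation (0.0837), and, as covariates chosen after seeing the data, with each array's difference of dim and bright probe sets (0.115) or the level of the X-linked gene Eif2s3 (0.0502). Whether the probes bind human huntingtin transcripts was not analysed here.

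**Figure D1:**
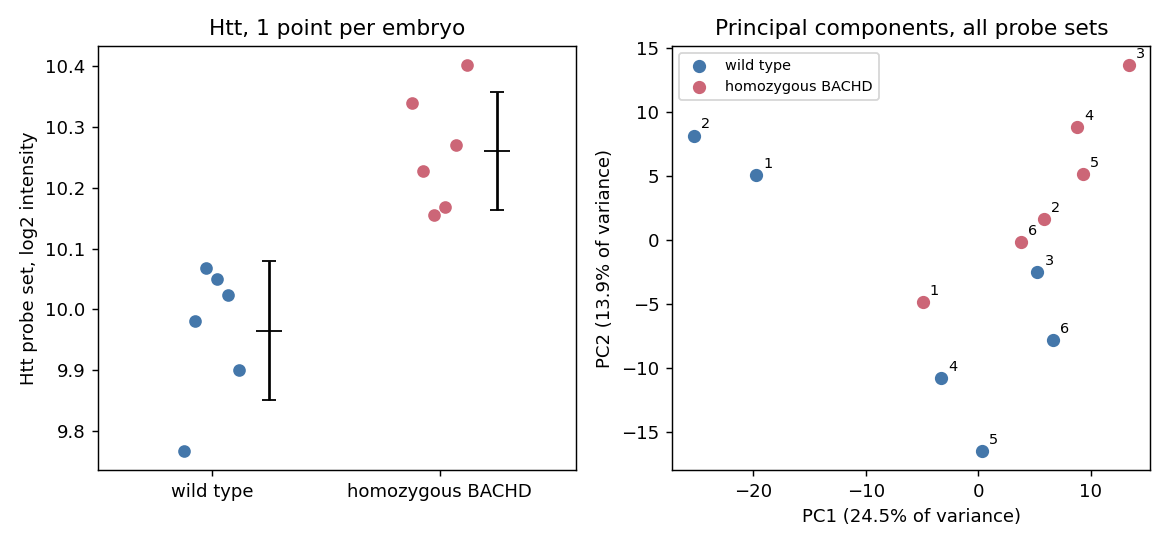
Left, log2 intensity of the Htt probe set for each embryo by genotype, with mean ± SD beside the points (n = 6 per group); all homozygous values, from 10.16 to 10.40, lie above the wild-type values, from 9.77 to 10.07. Right, the first against the second principal component of all probe sets (24.5% and 13.9% of the variance), 1 point per embryo with its replicate number; wild type 1 and 2 stand apart on the first component.

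Among genes that were higher in homozygous embryos, Pgk1, which makes the glycolytic enzyme phosphoglycerate kinase, rose by 0.32 ± 0.047 (log2, SE, n = 6 per group; 1.25-fold). Alkbh3, a demethylase that repairs alkylated nucleic acids, rose by 0.24 ± 0.034. These had the smallest adjusted p of the genes that rose, 0.0258 and 0.0254 in limma. Other genes that rose were Hmg20b, of the Lsd1 and CoREST complex (0.25 ± 0.038), Gtf2f1, a subunit of transcription factor IIF (0.23 ± 0.037), Pcid2, which takes part in mRNA export (0.22 ± 0.034), and Dnttip1, of a histone deacetylase complex (0.19 ± 0.031). Dpm3, of the dolichol-phosphate mannose synthase, rose by 0.19 ± 0.032, a value 2 probe sets gave identically, and Ttc39c by 0.22 ± 0.037. Smaller rises were seen for Cox7a2, of respiratory complex IV (0.12 ± 0.021), Idh3g, of mitochondrial isocitrate dehydrogenase (0.11 ± 0.020), and the ribosomal protein gene Rplp2 (0.16 ± 0.029). For Cox7a2 both probe sets passed and for Rplp2 all 3, but both genes have near-identical copies that could share probes, so their values are uncertain. Zfhx2, a homeobox gene, was read by 7 probe sets, all higher in homozygous embryos but by 0.06 to 0.20. The brightest differed by 0.06 ± 0.056 (adjusted p = 0.591), and 1 other passed, at 0.20 ± 0.031 (adjusted p = 0.0273).

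The genes that were lower in homozygous embryos were led by Nefl, the light subunit of neurofilaments, with a log2 intensity of 10.06 ± 0.112 in wild type and 9.64 ± 0.139 in homozygous embryos (SD, n = 6 each; 25.2% lower, adjusted p = 0.0273 in limma). Papss1, which makes the sulfate donor for sulfated glycans, fell by 0.31 ± 0.041 (log2, SE), and Mad2l1, of the spindle assembly checkpoint, fell by 0.22 ± 0.029. Both had an adjusted p of 0.0164, the smallest of the named genes. Cdkn2c, an inhibitor of cyclin-dependent kinases 4 and 6, fell by 0.21 ± 0.034. Tiprl, a regulator of phosphatase 2A, fell by 0.33 ± 0.053, and Fjx1, the homologue of fly four-jointed, fell by 0.30 ± 0.046. Cfap36 fell by 0.23 ± 0.037 and Ralgps2, an exchange factor for Ral, by 0.18 ± 0.030. Alg11, a mannosyltransferase of N-glycan synthesis, fell by 0.17 ± 0.028. The tetraspanin gene Tspan3, the translation initiation factor Eif1ax and the F-box gene Fbxo3 each fell by 0.16 ± 0.026, 0.026 and 0.027. With Htt, the 23 genes above that passed and 4 members of the gene lists (Id4, Ndufb8, Psma4 and Psma5), 28 named genes passed, and in each every homozygous value lay beyond every wild-type value. Of 25 other settings, Nefl did not pass in 11, Pgk1 in 10 and Papss1 in 4. None of the 28 changed direction with centred arrays, quantile normalization, cyclic loess or either covariate chosen after seeing the data; most other settings could not turn a direction, since the groups do not overlap or the difference stays the same by construction. Of the 28, the numbers that passed were 24, 26, 28, 11, 0 and 3 without wild type 1 to 6, and 4, 3, 3, 1, 1 and 22 without homozygous 1 to 6. None passed without an intensity trend, 1 with the dim and bright covariate and 12 with the level of Eif2s3.

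**Figure D2:**
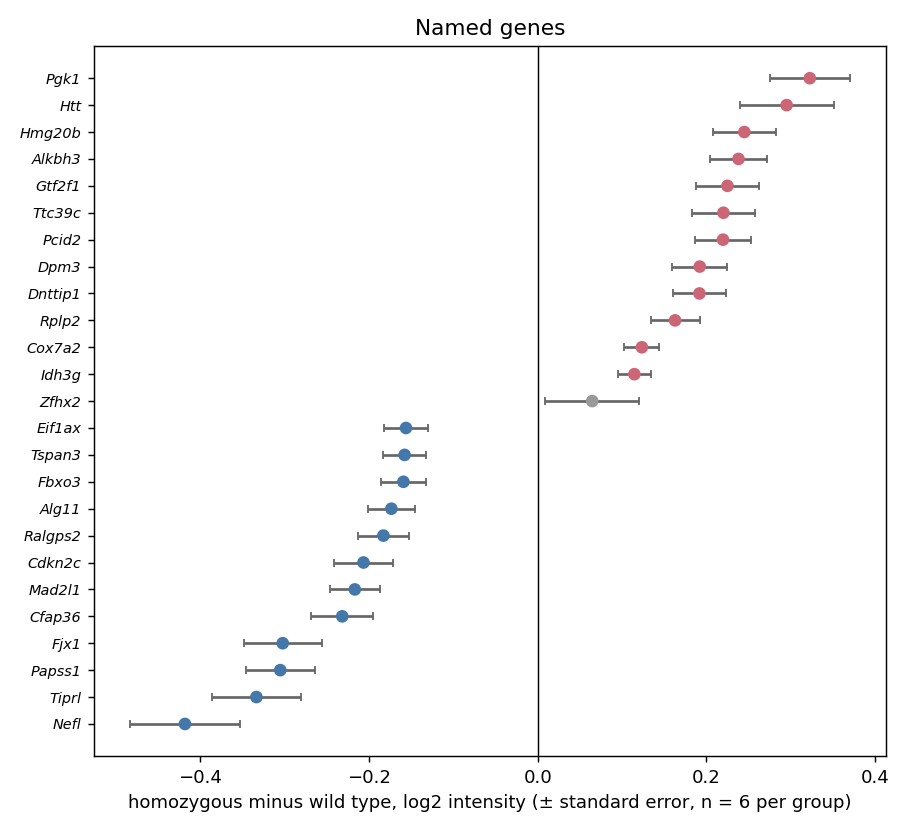
Difference between homozygous and wild-type embryos in log2 intensity (horizontal axis) for Htt and the 12 genes with the smallest p in each direction (vertical axis, by the probe set with the highest mean); points are differences of group means, bars are standard errors, n = 6 per group. Red points passed the adjusted threshold and were higher, blue points passed and were lower, and the grey point, Zfhx2 at 0.06, did not pass; Nefl at -0.42 is farthest from 0.

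In all, 124 of 29214 probe sets passed an adjusted p of 0.05 in limma, 66 higher and 58 lower in homozygous embryos. The 78 of these with 1 gene name stood for 72 genes, and 46 were unnamed here. Most differences were small: the median size was 1.15-fold, 32 probe sets differed by over 1.2-fold, and 1, an unnamed probe set, by over 2-fold. The latter was dim, with both group means below the array medians, so its size is uncertain. In 116 of the 124, the groups did not overlap. Over all probe sets 544 did not overlap, where chance gives 0.216% (63.2) on average. How widely this count varies over other splits of the arrays was not analysed, and probe sets are not independent. At an unadjusted p under 0.05 there were 4379 probe sets, 2974 higher and 1405 lower, but 1187 higher and 3087 lower with arrays centred on their medians. The split of the calls moved with the scaling, to 35 higher and 267 lower with arrays centred on their medians, 43 and 77 after quantile normalization, and 44 and 74 after cyclic loess, the last chosen after seeing the data. The number of calls changed strongly when single arrays were left out: it was 70, 200, 20, 4 and 14 without wild type 1, 3, 4, 5 and 6, and 10, 9, 9, 4, 4 and 59 without homozygous 1 to 6. It was 3 without an intensity trend in the variance and 1025 with the first residual component as a covariate and, in fits chosen after seeing the data, 582 without wild type 1 and 2, 6 with the dim and bright covariate and 29 with the level of Eif2s3.

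The gene lists fixed before the data were examined held 955 measured genes, of which 10 passed over all genes by their brightest probe set, 4 higher and 6 lower. None of the 36 lists with at least 5 measured genes passed camera's test against the other genes: the lowest adjusted p was 0.0571, with 6 lists at an unadjusted p under 0.05. With an estimated correlation the adjusted p was 0.831 or more and with fry 0.191 or more, so neither called a list. By fry's mixed test, which asks only whether members change in either direction, 17 lists passed. It does not compare members with other genes. Over all 29214 probe sets 4379 had an unadjusted p under 0.05, where chance gives 1461, so these lists need not stand out. Camera's direction is relative to the other genes, whose median difference was above 0 (0.02), so that 10 lists with a median above 0 tested downward. In 7 lists the mean and the test differed in sign.

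Genes that define the eminences themselves were measured without a change past the threshold. Of 16 genes of lateral eminence and striatal identity, none passed over all genes or adjusted over the list alone (camera adjusted p = 0.353). Mest and Isl1, a transcription factor of early striatal neurons, each differed by -0.10, with SE of 0.049 and 0.054. Of 23 genes of striatal projection neuron maturation none passed in either way (adjusted p = 0.250), with Rgs9 at 0.11 ± 0.047. Of 18 genes of the medial eminence and its interneurons none passed over all genes and 1 when adjusted over the list alone, the medial fate gene Nkx2-1 at 0.16 ± 0.040 (list adjusted p = 0.647). The 7 genes shared by subpallial GABAergic cells had none in either way (adjusted p = 0.945), with Dlx5 at -0.18 ± 0.080. Among 7 oligodendrocyte precursor genes none passed over all genes and 1 when adjusted over the list alone, Olig1 at -0.22 ± 0.068 (list adjusted p = 0.998).

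Of 38 genes of postmitotic neurons, Nefl fell and 37 did not pass over all genes. Adjusted over the list alone, 3 were lower and 2 higher, among them Nefm, the medium neurofilament subunit, at -0.21 ± 0.045. The list's adjusted p was 0.0787, and 0.831 with an estimated correlation. With 1 array left out it ranged from 0.00498 to 0.248 and passed in 3 of 12 cases, without wild type 6 (0.0181), homozygous 1 (0.0156) or homozygous 6 (0.00498). In the 13 other settings it ranged from 0.0538 to 0.884 and never passed. Of the pallial neuron markers, Neurod6 stood at -0.36 ± 0.105 and Slc17a7 at -0.25 ± 0.083, neither past the threshold (adjusted p = 0.145 and 0.187). Of 33 synaptic genes none passed over all genes and 1 when adjusted over the list alone, Syn1 for synapsin at 0.20 ± 0.041 (list adjusted p = 0.439). Syn1 was also the 1 gene to pass within the list of BDNF and REST-controlled genes (24 genes, list adjusted p = 0.609), in which none passed over all genes and Rest stood at 0.11 ± 0.041. Of 35 axon guidance genes none passed over all genes and 1 when adjusted over the list alone, Sema6d at -0.22 ± 0.053 (list adjusted p = 0.250).

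Among 19 radial glia and stem cell genes, Id4, an inhibitor of neuronal differentiation factors, fell by 0.20 ± 0.035 (adjusted p = 0.0303). Adjusted over the list alone, 5 were lower and 2 higher, including Ptn at -0.16 ± 0.043; the list's adjusted p was 0.250. Of 41 genes of G2 and M phase, Mad2l1 fell and 40 did not pass, with Plk1 at 0.07 ± 0.022, and Mad2l1 alone passed when adjusted over the list alone (list adjusted p = 0.833). Of 34 S phase genes none passed over all genes, but adjusted over the list alone 7 were higher and none lower, among them Rfc5 at 0.15 ± 0.032 and Chaf1b at 0.13 ± 0.028 (list adjusted p = 0.250). In the signalling lists no gene passed over all genes by its brightest probe set. Of the pathways, 1 of 27 Wnt genes passed when adjusted over the list alone, Tcf7l1 at 0.15 ± 0.038 (list adjusted p = 0.666), and none of 24 Notch genes (0.961; Hes5 0.15 ± 0.042), 8 Hedgehog genes (0.439; Sufu 0.12 ± 0.058) or 14 retinoic acid genes (0.912; Stra6 -0.16 ± 0.060). Of the 3 probe sets of Tcf7l1, only 1 passed over all genes, at 0.21. The third read -0.54 without passing, so the probe sets disagree and the direction for this gene is uncertain.

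Among 59 genes of oxidative phosphorylation, Cox7a2 rose and Ndufb8, of complex I, fell by 0.18 ± 0.034 (adjusted p = 0.0422), and 57 did not pass. Adjusted over the list alone, 4 were higher and 8 lower. The list stood lower with an adjusted p of 0.0571, and 0.831 with an estimated correlation. With 1 array left out the list's adjusted p at the correlation of 0.01 ranged from 0.0148 to 0.248 and passed in 7 of 12 cases, without wild type 3 (0.0169), 4 (0.0170), 5 (0.0339) or 6 (0.0148) or homozygous 1 (0.0156), 3 (0.0225) or 4 (0.0312). These are weak evidence, since other splits of the arrays gave a median of 5 lists past the same threshold. In the 13 other settings it ranged from 0.0182 to 0.905 and passed in 3, with arrays centred on their medians (0.0378), the mean of all probe sets of a gene (0.0433) and the level of Eif2s3 as a covariate (0.0182); the highest was without wild type 1 and 2. Of 36 glycolysis and hypoxia genes, Pgk1 rose and 35 did not pass; adjusted over the list alone 1 was higher and 2 were lower, including Pfkl at -0.12 ± 0.029 (list adjusted p = 0.609). Of 21 cholesterol synthesis genes none passed over all genes and 1 when adjusted over the list alone, the sterol sensor partner Insig1 at -0.28 ± 0.065 (list adjusted p = 0.250).

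In the proteasome list of 30 genes, Psma4 fell by 0.22 ± 0.037 and Psma5 by 0.20 ± 0.037, which encode subunits of the core particle (adjusted p = 0.0273 and 0.0388), and 28 did not pass. Adjusted over the list alone, 5 were lower and 2 higher; the list's median was 0.01, its test ran downward, and its adjusted p was 0.353. Of 66 ribosomal protein genes Rplp2 rose and 65 did not pass by their brightest probe set. Rps9, read by 3 probe sets, passed by a dimmer one at -0.14 ± 0.026 (adjusted p = 0.0440 in limma). Adjusted over the list alone 5 were higher and 11 lower, including Rps21 at -0.22 ± 0.046, and the list's adjusted p was 0.266. Of 20 genes for huntingtin and its partners, Htt rose, and adjusted over the list alone Hap1, which links huntingtin to transport along microtubules, passed too at 0.18 ± 0.041 (list adjusted p = 0.180). No gene passed over all genes in the other lists of protein quality and regulation. Among 27 unfolded protein response genes, 1 was lower when adjusted over the list alone, Dnajb9 at -0.16 ± 0.042 (list adjusted p = 0.250). Of 29 autophagy genes 2 were higher and 2 lower in the same way, with Becn1 at -0.10 ± 0.026 (0.698), and 1 of 26 immediate early genes was lower, Ier5 at -0.15 ± 0.037 (0.250). None passed in either way among 32 heat shock genes (0.250; Hsp90aa1 -0.07 ± 0.020), 30 histone deacetylases and acetyltransferases (0.434; Hdac1 0.11 ± 0.033), 27 genes of the p53 response (0.457; Mcl1 -0.10 ± 0.028) or 28 major histocompatibility genes (0.434; RT1-Da 0.14 ± 0.045).

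The 7 lists of neighbouring regions and other cell types held 179 measured genes, of which none passed over all genes in limma. Pallial genes had a median of -0.05 over 19 genes, led by Neurod6 and Slc17a7 (list adjusted p = 0.114, and 0.831 with an estimated correlation). With 1 array left out the list's adjusted p ranged from 0.00731 to 0.289 and passed in 3 of 12 cases, without wild type 5 (0.0104), wild type 6 (0.00731) or homozygous 1 (0.0259). In the 13 other settings it ranged from 0.0182 to 0.858 and passed in 1, with the level of Eif2s3. Choroid plexus and roof plate genes had a median of 0.07 over 19 genes, with Ttr at 0.17 ± 0.058 (list adjusted p = 0.180, and 0.831 with an estimated correlation). This ranged from 0.0156 to 0.289 with 1 array left out, passing only without homozygous 1, and from 0.0821 to 0.940 in the 13 other settings, with the direction turned under the dim and bright covariate. The globin genes Hbb and Hbb-b1 differed by -0.49 ± 0.147 and -0.64 ± 0.234, with an adjusted p of 0.155 and 0.232 (list 0.434, 25 genes). Of the 179 genes, 1 passed when adjusted over the list alone, the endothelial gene Cdh5 at 0.15 ± 0.033 (31 genes, list 0.945). The diencephalic list stood at 0.359 (26 genes; Gata2 0.18 ± 0.049), the mesenchymal list at 0.434 (31 genes; Col5a1 0.11 ± 0.040) and the microglial list at 0.391 (29 genes; P2ry12 -0.18 ± 0.049). Of Y-linked genes, Sry read 6.70 ± 0.0736 in wild type and 6.74 ± 0.139 in homozygous embryos (SD, n = 6 each), and Tspy1 6.08 and 6.10. Neither passed (adjusted p = 0.759 and 0.906).

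**Figure D3:**
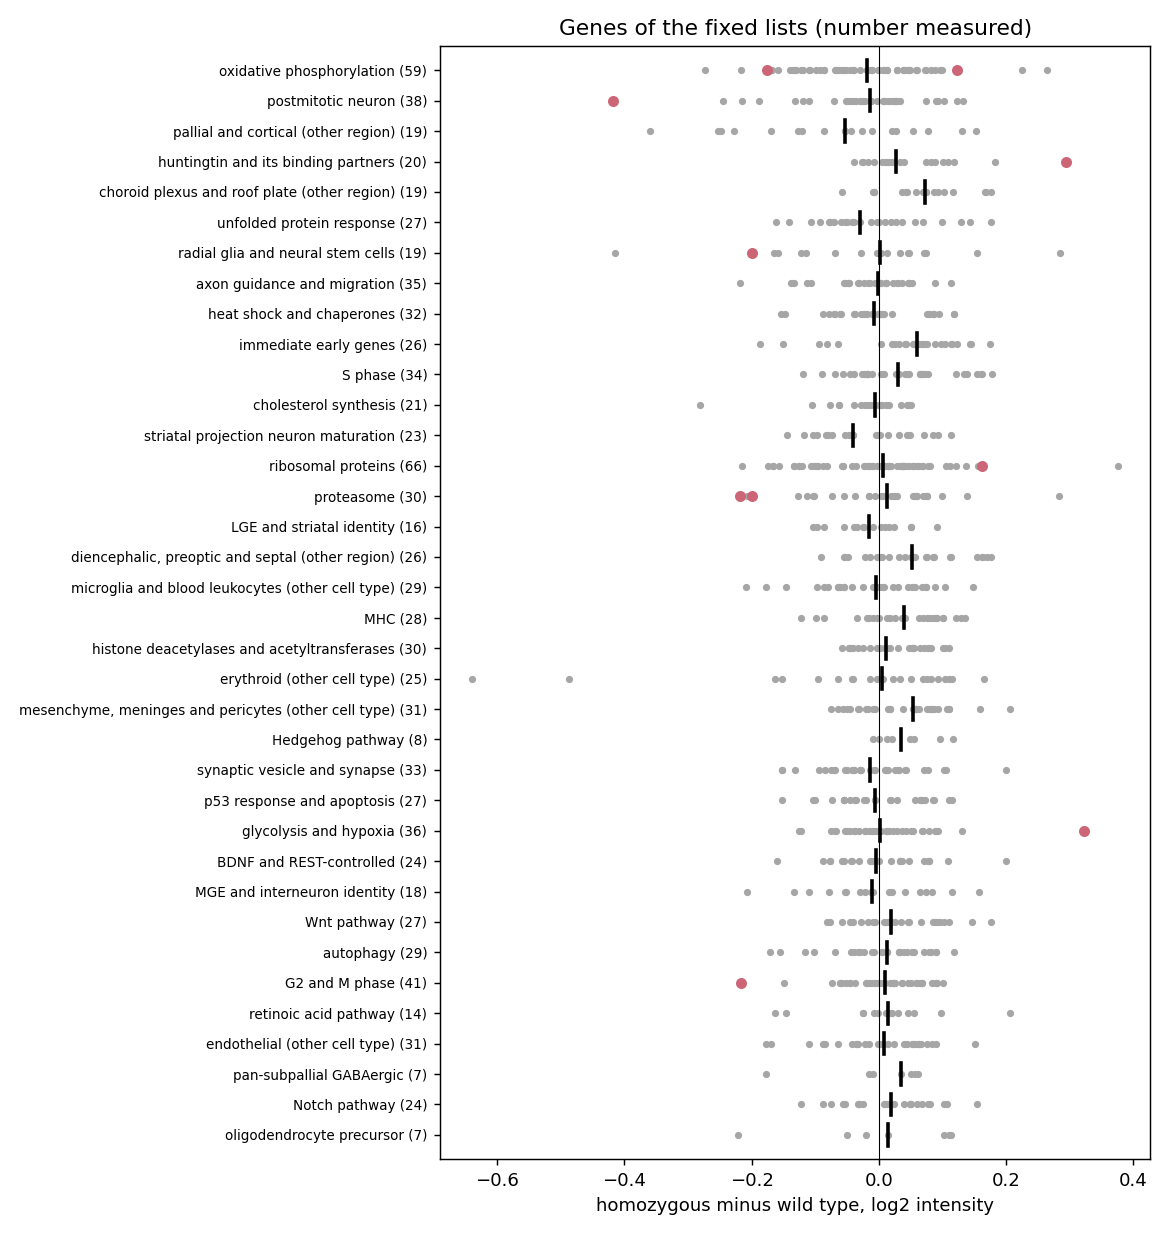
Difference between homozygous and wild-type embryos in log2 intensity (horizontal axis) for the measured genes of each list (vertical axis, number measured in brackets), 1 point per gene. Red points passed the adjusted threshold over all genes, grey points did not, and black bars are list medians; the medians farthest from 0 in each direction are 0.07 for choroid plexus and -0.05 for pallial genes, and no list passed its test.

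Whole profiles were farther apart between genotypes than within them, on average over both groups. The mean distance was 34.2 between groups, 35.2 among wild-type and 29.4 among homozygous embryos (Euclidean, log2), and the mean between groups exceeded that of all within-group pairs by 1.85 (exact permutation p = 0.0173 over 462 splits, 1-sided). It was 1.38, 0.83, 0.96, 1.01 and 1.43 without homozygous 2, 3, 4, 5 and 6, with exact p of 0.0801, 0.152, 0.139, 0.132 and 0.0714. Wild-type embryos varied more, at 22.8 ± 2.39 from their group's centre against 19.0 ± 2.03 (SD, n = 6 each), a difference of -3.80 (exact permutation of these distances with the centres kept, p = 0.0152, 2-sided). Wild type 1 and 2 stood apart on the first principal component, at -19.7 and -25.3, with the 10 other arrays between -4.94 and 13.4. The difference in spread was -3.47 without wild type 1 and -2.69 without wild type 2 (exact p = 0.0541 and 0.0736), and -1.23 (exact p = 0.324) without both.

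Because homozygous embryos share the chromosome around the transgene, the positions of changed genes were compared by the gene order of the rat assembly GRCr8. Of the 100 genes with the smallest p, at most 5 lay within 20 Mb: Alkbh3, Fjx1, Fbxo3, the synaptic adhesion gene Lrrc4c and the complement inhibitor gene Cd59b. The last 2 were named after their values were seen, at -0.29 ± 0.056 and -0.35 ± 0.069. In 10000 random draws of 100 of 14481 genes the median was also 5, and the permutation p was 0.868. The window held 90 of the 14481 genes, and at 10 Mb, 4 of the 100 lay in a window of 29. This test compares only the largest count in any window, which gene-dense windows can set in the draws. It can therefore miss a cluster among few genes, and linkage to the transgene stays open.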

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

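The tests of single samples below were set before the data were examined; the tests of explanations were chosen after the results were seen. In 7 of 184 groups of 6 embryos, 1 embryo lay far from the others, by a gap of more than 0.625 of the group's range. About 9.2 would do so by chance, since chance marks about 1 in 20. In wild type, Ttc39c read 9.12 in embryo 3 against 8.97 to 9.02 in the others (gap 0.680 of the range). Ralgps2 read 10.51 in wild type 4 against 10.41 to 10.43 (0.762). The chaperone gene Hsp90aa1 read 12.69 in wild type 3 against 12.74 to 12.77 (0.653), and the survival gene Mcl1 read 11.71 in wild type 5 against 11.61 to 11.63 (0.799). Among homozygous embryos, embryo 2 stood low for both Eif1ax, 10.97 against 11.02 to 11.04 (0.689), and the growth factor gene Ptn, 10.75 against 10.94 to 11.01 (0.734). The apoptosis gene Bax read 9.34 in homozygous 6 against 9.40 to 9.43 (0.640).

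The higher Htt signal was weighed against 2 technical explanations. A difference between arrays that depends on intensity predicted that the Htt difference would shrink after cyclic loess, but it was 0.29 on the log2 scale against 0.30 before, with every homozygous embryo above every wild-type embryo in the deposited values. Binding of human transgene transcripts to the rat probes could also raise the signal. With 1 Htt probe set on the table, this cannot be told apart from higher expression of the rat gene, since there was no second Htt probe set for comparison and where the probes lie was not analysed here. An effect of the transgene on rat Htt stays open as a hypothesis.

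The lower Nefl signal may come from a smaller share of postmitotic neurons. That would lower the other neuron genes together, but the median difference of the 37 others was -0.0128 on the log2 scale, with quartiles of -0.0459 and 0.0249, against -0.42 for Nefl. These values argue against a general loss of neurons as the whole cause. Nefm stood at -0.21, and the pallial neuron markers Neurod6 and Slc17a7 at -0.36 and -0.25, without passing. Loss of only some neurons, such as the most mature or those of neighbouring pallium in the dissected tissue, and less Nefl per neuron in the homozygous genotype stay open and were not tested.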

How the results depend on the processing

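The count of 124 calls was, with calls shared in brackets, 18 with a replicate block (12 shared), 208 above the 30th percentile (116), 302 with arrays centred on their medians (91), 3 without an intensity trend, 74 without variance moderation (52), 414 with array weights (124), 1025 with the first residual component (124) and 32 with a 1.2-fold minimum. Among those chosen after seeing the data it was 582 without wild type 1 and 2 (120), 6 with the dim-minus-bright covariate (5) and 29 with the level of Eif2s3 as a covariate (26). With 1 array left out it lay between 4 (without wild type 5, homozygous 4 or homozygous 5) and 200 (without wild type 3). Cyclic loess gave 118 (99) and quantile normalization 120 (95). All 124 kept their direction and an unadjusted p under 0.05 with centred arrays, quantile normalization, cyclic loess and either added covariate; they were chosen for small p, and most other settings could hardly turn a direction. The cause of the changes in count was not tested. The Htt difference had an adjusted p over 0.05 with the block (0.30, p 0.130), centred arrays (0.26, p 0.0555), no trend (0.30, p 0.0890), no moderation (0.30, p 0.0837), the dim-minus-bright covariate (0.31, p 0.115) and the Eif2s3 level (0.32, p 0.0502), and lay between 0.26 and 0.32 with 1 array left out (adjusted p 0.0338 to 0.0864). From 0 lists, 1 passed with centred arrays and 1 with the mean of all probe sets, both times oxidative phosphorylation, 2 with the Eif2s3 level (oxidative phosphorylation and pallial genes, both lower, adjusted p = 0.0182), and 0 to 4 with 1 array left out. With an estimated correlation none passed in the deposited values (adjusted p of 0.831 or more). The separation of profiles lay between 0.83 and 2.97 with 1 array left out, past the threshold in 7 of 12. The difference in spread lay between -4.63 and -2.69, past it in 10 of 12, and was -1.23 without wild type 1 and 2. Clustering along the chromosomes did not pass at any window or number of genes, by a test of the largest count that can miss a cluster among few genes. Of 700 values of 28 genes named besides Htt, Zfhx2 included, under 25 alternatives, 396 stayed on the same side of the threshold, 303 no longer passed, 1 newly passed and 0 reversed. Of the 28 named genes that passed, Htt included, 3 passed with the block, 23 with centred arrays, 20 without moderation and 27 after quantile normalization. Numbers shared between groups showed no clear pairing of embryos, though 6 pairs cannot exclude a partial one. The correlations of same-numbered arrays were -0.0817 to 0.256, with 2 of 6 over 0.1, against a mean of -0.00713 for other numbers. Of the arrays, 2 wild-type and 1 homozygous correlated best with their own number. The planned covariate of Y-linked genes was not run, since the genes it names were not among the named probe sets. Signal over background was not analysed here, so the precision of dim probe sets rests on the spread between arrays.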

Other observations

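The tests of explanations in this part were chosen after the results were seen, except that of the gene lists over other splits. Beyond the genes named by rule, and chosen after their values were seen, further genes passed the adjusted threshold in limma. Antxr1, a collagen and anthrax toxin receptor, was higher by 0.37 ± 0.075 (log2, SE, n = 6 per group) and the nucleoside transporter gene Slc28a2 by 0.37 ± 0.069. The adhesion gene Lrrc4c stood at -0.29 and the phosphatase gene Dusp19 at -0.33. Rheb, the small GTPase that activates mTORC1, stood at -0.20 ± 0.039, and Vps35, of the retromer, at -0.13. Prkar2b, a regulatory subunit of protein kinase A, stood at -0.23. The microtubule end-binding gene Mapre3 was higher by 0.20 and the centriole gene Poc1a by 0.22. Rpl41 was lower in 2 of its 3 probe sets, at -0.23 and -0.20, but has many near-identical copies, so its value is uncertain. The largest log2 difference in the deposited values was that of an unnamed probe set, 10701023, at 4.71 ± 1.13 in wild type and 7.16 ± 0.299 in homozygous embryos (SD, n = 6 each), with wild-type embryos reaching 6.84 and homozygous embryos starting at 6.66. Another unnamed probe set, 10906451, read 5.12 ± 0.420 and 6.09 ± 0.166. All these means lay below the array medians of 7.67 to 7.76, and signal over background was not analysed here, so both sizes are uncertain and no exact fold is given.

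Eif2s3, an X-linked gene that escapes X inactivation in the mouse, fell into separate levels. It lay between 12.70 and 12.90 in 7 embryos, 3 wild type and 4 homozygous, and between 12.51 and 12.54 in 5 embryos, 3 wild type and 2 homozygous. The X-linked genes Ddx3x and Usp9x ranged from 12.13 to 12.40 and from 11.41 to 11.61. None of the 3 differed between genotypes by more than its spread (adjusted p = 0.649, 0.906 and 0.811).

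The number of calls was set against other splits of the 12 arrays into 6 and 6. Of 100 of the 462 splits, the real one included, 1 gave as many as 124 probe sets, the real one. The highest other gave 15, which argues against a chance assignment of the arrays in the main fit. Other fits were not compared in this way, and without an intensity trend the real split gave 3. The dam of each embryo was not in the labels, so a difference between litters that went along with genotype cannot be told apart here. At an unadjusted p under 0.05, 4 of 100 reached 4379, and the highest other reached 6012. For gene lists the real split gave 0, which all 100 reach by construction, so this comparison says nothing about chance. The highest other gave 12 lists, the median of the others was 5, and 6 of the others gave none. Camera's preset correlation was 0.01, while the estimate was 0.163 for oxidative phosphorylation and 0.193 for postmitotic neuron genes. It was lower in some lists, such as -0.00586 for oligodendrocyte precursor genes. Where genes of a list move together more than the preset allows, lists can pass too easily.

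More probe sets read higher than lower in homozygous embryos, 67.9% of those at an unadjusted p under 0.05, as deposited. The share was 27.8% with arrays centred on their medians and 46.7% after quantile normalization, so it depended on the scaling. Both bring the median difference of all probe sets near 0 (-0.00847 and 0.00251), so they cannot show which direction is right. After cyclic loess the share was 47.05%, but that scaling also centres all probe sets near 0. It therefore does not test whether an intensity-dependent difference between arrays, left by the normalization, is the cause. With the dim and bright covariate, which does not centre them, the share was 62.7%, and over all probe sets it went from 64.8% to 56.2% and their median log2 difference from 0.03 to 0.01. Without wild type 1 and 2 the share at an unadjusted p under 0.05 was 65.4%, so these arrays alone do not account for it. A difference left by the normalization and an effect of genotype on many transcripts both stay open.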
